A study of Mus musculus with 12 samples.

How the data were processed

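The data are whole-liver RNA sequencing values of 12 mouse libraries in 4 groups of 3 (HFHS, HFHS with curcumin liposomes, HFHS with calcitriol liposomes, and a group titled CNT). Each library came as a deposited table of gene identifiers and log2 values, made by the authors before deposit. STAR 2.4.0d, DESeq2 1.8.1 and the mouse build GRCm38 are named in the submitters' processing notes, without their roles. Neither the files nor the labels name the transformation. The values run from -3.63 to 20.7, no gene is at 0 in some libraries only, and low genes sit close to a floor of their own. This is the pattern of a regularized log2 transformation, so the fold changes of weakly expressed genes are probably pulled toward 0. Counts were not used here, so the depth of each library is unknown and no counting interval is given; what can be given is the spread between libraries, with a median standard error of 0.100 (log2) for a difference between 2 groups.

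The same gene identifiers were present in every file, and 23411 of them were listed at exactly 0 in all 12 libraries and were left out. Symbols and coordinates came from the GENCODE M21 annotation of GRCm38, which names all but 649 of the 22381 others (37 of those tested). Genes were tested where the value reached log2 of 10, or 3.32, in at least 3 libraries, which left 12637 genes. Group labels were taken from the sample titles. No further scaling was applied.

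The tests planned before the data were examined assumed read counts. Because the deposited values are on a log2 scale, limma 3.58.1 in R 4.3.3 was used instead, with the groups and contrasts as planned: a linear model with 4 group means over all 12 libraries, empirical Bayes moderation with a trend and robust estimation, two-sided tests, and Benjamini-Hochberg adjustment over all genes tested, with a threshold of 0.05. All 4 groups share 1 estimate of the spread. The filter and the limma options were set after the files had been read and after a first run with another filter, on a mean value of at least 4, had been seen. That run called 122, 258, 1426 and 0 genes in the comparisons of curcumin with HFHS, calcitriol with HFHS, HFHS with CNT, and curcumin with calcitriol. Standard errors are those of the moderated model, except for the means of gene lists in the closing observations, where the SE over genes and the SE between libraries are named as such.

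Gene lists were fixed before the data were examined: 41 lists of pathways and cell types, of which 39 had at least 5 tested genes (26 pathway and 13 cell type lists of 5 to 32 genes; 13 list members were at 0 or not found). They were tested with limma's camera, a competitive test, with a preset correlation of 0.01 between genes, and adjusted over the 39 lists of each comparison. Camera with a correlation estimated for each list is given beside it. For fry, a self-contained test of whether a list's genes move one way, the number of lists past the threshold is given for each comparison. Its adjusted p is printed for some lists only. The estimated correlations include the differences between libraries that many genes share, and nearly all list calls were lost with them: 0, 0, 0 and 1 lists passed in the 4 comparisons. A count "adjusted over the list alone" is a Benjamini-Hochberg adjustment within that list. A list score is the mean, over the list's genes, of each library's deviation from the gene's mean over 12 libraries.

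The rule for the genes named in the text was fixed before the data were examined. In each comparison it takes the 8 largest rises and the 8 largest falls among genes past the threshold with a named symbol, a mean of at least 0 on a log2 CPM scale made from the deposited values, and groups that do not overlap. It adds up to 4 members, those with the smallest p, of each list that passed or that held at least 3 called genes. Where no gene passed, it takes the 10 named genes with the smallest p as values only. Vdr, Cyp24a1, Nfkbia, Tnf, Il1b, Ccl2, Cd68, Col1a1, Hmox1 and Nqo1 are always given, with Scd1, Fasn, Cidec and Cyp7a1 added for HFHS against CNT, and beyond about 30 genes the text leaves out names from the end of the ranking. Mt1 and Mt2 in the curcumin comparison, Mir22hg where both treatments are set side by side, and Cfd, Slc30a1, Slc39a10 and the clock genes, named in the account of single libraries or in the closing observations, were chosen after their values were seen.

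The model was tested on simulated data with the means and spreads of the real libraries and 200 genes changed. A log2 change of 1 was recovered for 90% of genes (curcumin with HFHS), 91% (calcitriol with HFHS), 91% (HFHS with CNT) and 94% (curcumin with calcitriol), and a change of 0.5 for 59%, 53%, 69% and 66%, with 12, 7, 10 and 9 false calls among 12637 genes. The same spread was used for all groups, so the simulation does not cover the wider spread of the HFHS libraries. Genes were drawn independently of each other, so differences between libraries that many genes share are not covered either.

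Alternatives were a stricter filter (1 CPM in 6 libraries), no filter, only the 2 groups compared in the fit, the replicate number as a block, each library left out in turn, and the list tests above. The highest p of a list is over quantile normalization, the replicate block, each of the 6 libraries left out and, in comparisons with HFHS, HFHS replicates 1 and 3 left out. Chosen after seeing the data were median centring, quantile normalization, moderation without robust estimation, the filter on a mean of at least 4, library weights, leaving out HFHS replicates 1 and 3, a simulation with the spread of HFHS alone, and the comparisons of both treated groups with CNT. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.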

Results

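Gene expression was measured by RNA sequencing in whole livers of female C57BL/6 mice, an inbred laboratory strain. The mice received a diet high in fat and sugar (HFHS) for 14 weeks, a feeding model of fatty liver with inflammation (steatohepatitis). Liposomes carrying curcumin, a plant polyphenol, or calcitriol, the hormonally active form of vitamin D, were injected into a vein at weeks 12 and 13, and livers were taken 2 weeks after the first injection. The 12 libraries fall into 4 groups of 3: HFHS without treatment, HFHS with curcumin liposomes, HFHS with calcitriol liposomes, and a group titled CNT. The sample labels give the CNT group the same diet text as the others, so what sets it apart from HFHS is not stated in the sources used here, and it is called by its title. Groups given empty liposomes were not analysed here. Effects of curcumin or calcitriol therefore cannot be told apart from those of the injections and the liposomes. The values are log2 expression levels without counts, so the sequencing depth of each library is unknown. From the pattern of the values, fold changes of weakly expressed genes are probably understated. Values were given for 22381 genes, of which 12637 were expressed highly enough to be tested. The titles do not say that the 3 libraries of a group are separate animals, so p-values measure the spread between these samples.

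The HFHS libraries differed from each other more than those of any other group. The SD between libraries within a group was 0.233 on the log2 scale in HFHS, 0.177 in CNT, 0.148 with calcitriol and 0.126 with curcumin. HFHS replicates 1 and 3 lay apart on the first principal component, at -32.9 and -28.5, while HFHS replicate 2, at 3.09, lay among the libraries of the other groups. Collagen and macrophage genes followed the same division. Col1a1, the main chain of type I collagen, stood at 10.13 and 9.78 in HFHS replicates 1 and 3 and at 7.33 in replicate 2. Gpnmb, a glycoprotein of lipid-laden macrophages, stood at 8.62, 7.15 and 4.89 in HFHS replicates 1, 3 and 2. HFHS replicate 3 also had a high level of the adipocyte gene Cfd, 9.18 against at most 4.32 in the other 11 libraries.

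**Figure D1:**
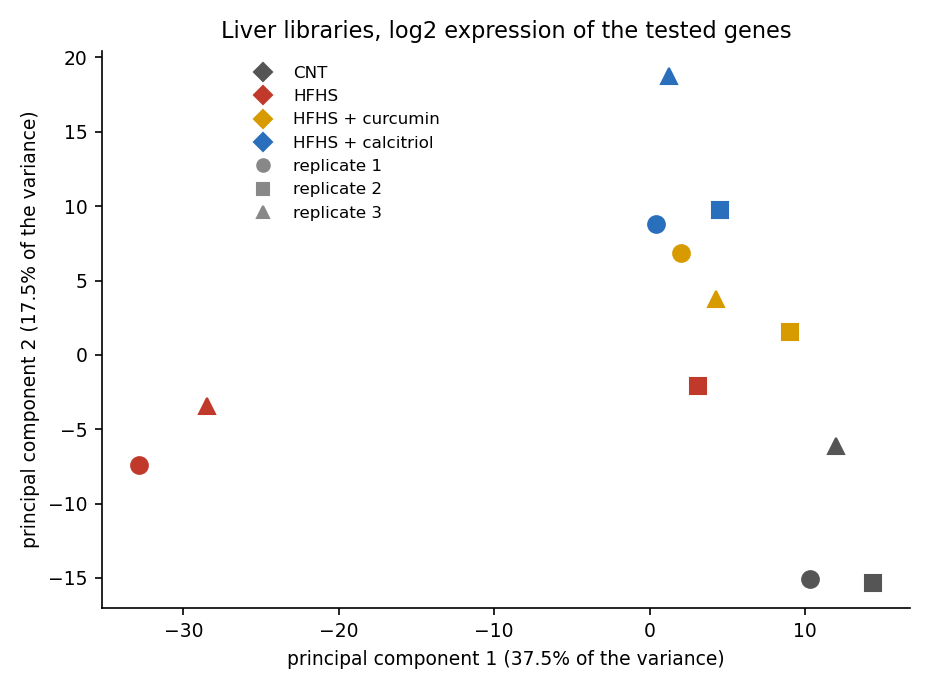
Position of the 12 liver libraries on the first and second principal components of log2 expression, which hold 37.5% and 17.5% of the variance; color marks the group and shape the replicate number. HFHS replicates 1 and 3 lie at -32.9 and -28.5 on the first component and all other libraries between 0.396 and 14.4.

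Untreated HFHS livers were compared with those titled CNT to see how these groups differed. Genes of macrophages, matrix and fat storage were higher in HFHS. The largest rises were in Gpnmb (log2 change 2.64 ± 0.71 SE, adjusted p = 0.0427), Ly6d (2.54 ± 0.54), Cidec (2.30 ± 0.29, adjusted p = 0.00342), the macrophage elastase Mmp12 (1.95 ± 0.47), the elastin gene Eln (1.89 ± 0.54), the collagen gene Col3a1 (1.89 ± 0.51), the lipoprotein lipase Lpl (1.75 ± 0.38) and Osbpl3 (1.66 ± 0.36). Cidec, which encodes a protein that enlarges lipid droplets (ENSMUSG00000030278, GRCm38 chromosome 6, 113424634 to 113435760, minus strand), averaged 7.67 ± 0.71 in HFHS and 5.37 ± 0.14 in CNT (log2, mean ± SD, n = 3 each). The largest falls were in Serpina1e (-3.38 ± 0.39, adjusted p = 0.00342; chromosome 12, 103946931 to 103958975), an alpha-1-antitrypsin gene, and in the sulfotransferase genes Sult3a1 (-2.79 ± 0.55) and Sult5a1 (-2.28 ± 0.18, adjusted p = 0.000122). Cyp2c54 (-1.97 ± 0.33), Cyp2c69 (-1.89 ± 0.29), Mup16 (-1.88 ± 0.49), Tiam2 (-1.86 ± 0.29) and Ces3b (-1.83 ± 0.38) fell as well. Serpina1e, Sult3a1, Mup16 and the Cyp2c genes have near-identical relatives that could share reads, so their values are uncertain.

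Fat handling genes moved in several directions between HFHS and CNT. In the lipid droplet and fat storage list, 6 of 20 measured genes rose over all genes tested, and 7 rose and 1 fell adjusted over the list alone. They included Cd36, a fatty acid transporter (1.20 ± 0.12, adjusted p = 0.000871), the adipogenic receptor Pparg (0.77 ± 0.10) and the droplet coat gene Plin4 (1.49 ± 0.28). The list was higher in HFHS by limma's camera (adjusted p = 0.00199), with adjusted p = 0.5 with an estimated correlation. In the fatty acid oxidation and ketogenesis list 7 of 24 rose, and 7 adjusted over the list alone, among them Vnn1 (0.99 ± 0.11), Cyp4a14 (0.82 ± 0.15) and the hormone gene Fgf21 (1.04 ± 0.17). By camera the fatty acid oxidation list had adjusted p = 0.000292, and adjusted p = 0.504 with an estimated correlation. De novo lipogenesis was lower: 4 of 18 fell, and 7 fell and 1 rose adjusted over the list alone, including Fasn, which encodes fatty acid synthase (-0.83 ± 0.17, adjusted p = 0.0177), Elovl6 (-0.78 ± 0.17) and Srebf1 (-0.59 ± 0.18). By camera the lipogenesis list had adjusted p = 0.00496, and adjusted p = 0.504 with an estimated correlation. Scd1, a desaturase, had a log2 change of -1.14 ± 0.47 (adjusted p = 0.127). In bile acid synthesis and transport 4 of 19 fell, and 8 adjusted over the list alone (list adjusted p = 0.00391, or 0.504 with an estimated correlation), while Cyp7a1, the rate-limiting enzyme of bile acid synthesis, had -0.08 ± 0.26 (adjusted p = 0.859).

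Inflammatory, matrix and cell cycle lists were higher in HFHS than in CNT. In the fibrosis and extracellular matrix list 12 of 31 genes rose, and 28 rose and 1 fell adjusted over the list alone, with Col4a1 (1.15 ± 0.22) and Thbs2 (1.39 ± 0.27) among the 12. By camera the fibrosis list had adjusted p = 4.37e-12, and adjusted p = 0.504 with an estimated correlation. Col1a1 itself had 2.11 ± 0.62 (adjusted p = 0.054). Antigen presentation by MHC class II showed 7 of 9 genes up, and 9 adjusted over the list alone, for example Cd74 (0.99 ± 0.25). By camera the MHC class II list had adjusted p = 4.94e-06, and adjusted p = 0.504 with an estimated correlation. In the monocyte-derived macrophage list 7 of 14 rose and 1, F10, fell, and 11 rose and 1 fell adjusted over the list alone, with Trem2 at 1.08 ± 0.24. By camera the macrophage list had adjusted p = 5.44e-05, and adjusted p = 0.504 with an estimated correlation. Of the NF-kB targets 8 of 20 rose, and 11 adjusted over the list alone, including Ccl5 (1.12 ± 0.20), Il1b (0.75 ± 0.18, adjusted p = 0.0268) and Tnfaip3 (0.86 ± 0.22). By camera the NF-kB list had adjusted p = 3.63e-05, and adjusted p = 0.504 with an estimated correlation. Ccl2 (0.63 ± 0.16, adjusted p = 0.0327) and the macrophage gene Cd68 (0.62 ± 0.13, adjusted p = 0.0188) rose, while Hmox1 (0.56 ± 0.18, adjusted p = 0.0591), Nqo1 (0.28 ± 0.13, adjusted p = 0.173) and Nfkbia (0.07 ± 0.12, adjusted p = 0.684) did not pass. In the cell cycle list 11 of 25 rose, and 18 adjusted over the list alone, led by the replication licensing genes Mcm5 (1.04 ± 0.13, adjusted p = 0.00325) and Mcm6 (1.06 ± 0.14). By camera the cell cycle list had adjusted p = 5.16e-08, and adjusted p = 0.504 with an estimated correlation. In the periportal hepatocyte list 8 of 15 fell and 1, Apoa4, rose, and 11 fell and 1 rose adjusted over the list alone, including the urea cycle genes Asl (-0.96 ± 0.19) and Cps1 (-0.84 ± 0.18). By camera the periportal list had adjusted p = 0.000183, and adjusted p = 0.504 with an estimated correlation. Its score was -0.91 in HFHS replicate 3, the library with high Cfd and an adipocyte score of 1.85, against -0.04 and 0.10 in HFHS replicates 1 and 2 and at least 0.28 in CNT. In the general hepatocyte list 4 of 14 fell, and 6 adjusted over the list alone. By camera the hepatocyte list had adjusted p = 0.00192, and adjusted p = 0.504 with an estimated correlation, and 0.334 under quantile normalization, the highest of 9 settings. Among female-biased liver genes 4 of 17 fell, over all genes tested and adjusted over the list alone, with Cux2 at -0.87 ± 0.15 (adjusted p = 0.0109). By camera the female-biased list had adjusted p = 0.0128, and adjusted p = 0.504 with an estimated correlation.

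Across all genes 828 rose and 677 fell in HFHS at an adjusted p under 0.05 in limma, of which 58 rose and 34 fell at least 2-fold, and the 3 libraries of each group did not overlap for 26.9% of genes, where chance gives 10%. The fibrosis and macrophage differences were carried mostly by HFHS replicates 1 and 3: their fibrosis list scores were 1.22 and 1.08 against -0.16 in HFHS replicate 2 and -0.39 to -0.23 in CNT. The 1505 calls became 3717 without HFHS replicate 2, 216 without HFHS replicate 1, 269 without HFHS replicate 3, 538 and 135 without CNT replicate 1 or 2, 13 with only these 2 groups in the fit, and 68 without HFHS replicates 1 and 3, where the lone HFHS library is assumed to vary like the other groups. Over 15 other settings, each with at least 2 HFHS libraries, the adjusted p was 2.93e-05 to 0.0209 for Serpina1e, 6.79e-07 to 0.0174 for Sult5a1, 7.99e-05 to 0.0394 for Cd36 and 0.00169 to 0.0444 for Cux2. Cidec (1.78e-05 to 0.0615) passed in 14 of the 15, and Gpnmb (0.000103 to 0.154) in 7. Over 9 settings of the list test, leaving out HFHS replicates 1 and 3 gave the highest adjusted p for the macrophage (0.0555), NF-kB (0.0811), de novo lipogenesis (0.927), bile acid (0.438), female-biased (0.554), fibrosis (0.00247), MHC class II (0.0156) and cell cycle lists (0.000673). Quantile normalization kept the direction of the de novo lipogenesis, bile acid and female-biased lists and gave adjusted p = 0.217, 0.103 and 0.0681.

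The curcumin comparison asks what the liposomal treatment changed in HFHS livers. Curcumin livers had higher Aatk (1.41 ± 0.23, adjusted p = 0.0384), a kinase gene, and Fbxo31 (1.18 ± 0.19, adjusted p = 0.0384), which encodes a subunit of a ubiquitin ligase. Smaller rises were seen in Elmod3 (0.68 ± 0.12), Coa6 (0.68 ± 0.12), a cytochrome oxidase assembly factor, Mir22hg (0.65 ± 0.10), the sphingosine kinase Sphk2 (0.65 ± 0.11), Fpgs (0.63 ± 0.12) and the adrenergic receptor Adra1a (0.60 ± 0.08). The lowest adjusted p belonged to Shank2, a scaffold protein gene (ENSMUSG00000037541, GRCm38 chromosome 7, 144001928 to 144424494), which averaged 7.39 ± 0.20 with curcumin and 8.39 ± 0.24 in HFHS (log2, mean ± SD, n = 3 each; change -0.998 ± 0.118, adjusted p = 0.0238). Mcm6 (-0.86 ± 0.14) and Mcm5 (-0.79 ± 0.13), Maged2 (-0.82 ± 0.14), Cnn2 (-0.74 ± 0.14), the heat shock gene Hspa1b (-0.71 ± 0.11), the chromatin remodeller Hells (-0.68 ± 0.11) and Creb3l2 (-0.64 ± 0.11) fell. Hspa1b has a near-identical neighbour, Hspa1a, so its value is uncertain.

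Cell cycle genes were lower as a group with curcumin: Mcm5 and Mcm6 fell over all genes tested, and 14 of 25 fell adjusted over the list alone. By camera the cell cycle list had adjusted p = 3.53e-09, and adjusted p = 0.519 with an estimated correlation. All 22 cholesterol synthesis genes had log2 changes below 0, with a median of -0.40, 0 passing over all genes tested and 14 falling adjusted over the list alone. Lss, which encodes lanosterol synthase, had -0.57 ± 0.12 (adjusted p = 0.051). By camera the cholesterol synthesis list had adjusted p = 1.07e-08, and adjusted p = 0.519 with an estimated correlation. All 32 oxidative phosphorylation genes had changes above 0, with a median of 0.25 and 0 passing either adjustment. By camera the oxidative phosphorylation list had adjusted p = 2.31e-09, and adjusted p = 0.519 with an estimated correlation. The highest over 9 settings was 0.484, without HFHS replicates 1 and 3. In the fibrosis and extracellular matrix list 30 of 31 genes had changes below 0, 0 passed over all genes tested and 24 fell adjusted over the list alone. Thbs2 had -0.95 ± 0.27 (adjusted p = 0.0912) and Col1a1 -1.56 ± 0.62 (adjusted p = 0.164). By camera the fibrosis list had adjusted p = 1.11e-10, and adjusted p = 0.519 with an estimated correlation. MHC class II genes (median -0.51, 0 of 9 passing and 9 falling adjusted over the list alone) and macrophage genes (median -0.64, 0 of 14 passing and 6 falling adjusted over the list alone) were lower by camera (adjusted p = 9.13e-05 and 0.000143, or 0.519 for each with an estimated correlation). Over 9 settings the highest adjusted p of the fibrosis, MHC class II and macrophage lists, 0.884, 0.986 and 0.884, came from leaving out HFHS replicates 1 and 3, where the direction of the fibrosis list turned, while those of the cell cycle and cholesterol synthesis lists were 0.00247 and 0.00179. NRF2 antioxidant targets (median -0.28, 0 of 23 passing and 5 falling adjusted over the list alone) and interferon response genes (median -0.25, 0 of 26 passing and 3 falling adjusted over the list alone) were lower by camera as well (adjusted p = 0.000754 and 4.03e-05, or 0.519 for each with an estimated correlation). Mt2 and Mt1, metallothionein genes, had 1.89 ± 0.37 (adjusted p = 0.051) and 1.56 ± 0.35 (adjusted p = 0.0665). Il1b (-0.31 ± 0.18, adjusted p = 0.298), Ccl2 (-0.39 ± 0.16, 0.171), Cd68 (-0.36 ± 0.13, 0.133), Nfkbia (-0.07 ± 0.12, 0.752), Hmox1 (-0.24 ± 0.18, 0.424) and Nqo1 (-0.28 ± 0.13, 0.214) did not pass.

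Cell type lists also moved with curcumin. All 8 erythroid genes had changes above 0, with a median of 0.62, 0 passing over all genes tested and 4 rising adjusted over the list alone. By camera the erythroid list had adjusted p = 0.000329, and adjusted p = 0.519 with an estimated correlation. In the hepatocyte list 12 of 14 genes had changes above 0, with 0 passing either adjustment, and the direction turned under quantile normalization (adjusted p = 0.886) and without HFHS replicates 1 and 3 (0.984, the highest of 9 settings). By camera the hepatocyte list had adjusted p = 0.02, and adjusted p = 0.575 with an estimated correlation. In the liver endothelial list 17 of 18 had changes below 0, with 0 passing either adjustment. By camera the endothelial list had adjusted p = 0.011, and adjusted p = 0.645 with an estimated correlation, with a highest value over 9 settings of 0.317 without HFHS replicate 3.

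With curcumin 19 genes rose and 19 fell at an adjusted p under 0.05 in limma, 3 of them rising at least 2-fold, and groups did not overlap for 23.6% of genes, where chance gives 10%. The 38 calls became 3207 without HFHS replicate 2, 0 without HFHS replicate 1 or 3 (1793 and 1887 genes at an unadjusted p under 0.05), 2, 0 and 0 without curcumin replicate 1, 2 or 3, 0 with only the 2 groups in the fit (lowest adjusted p = 0.139, 2467 genes at an unadjusted p under 0.05), and 0 without HFHS replicates 1 and 3. Of 39 lists, 8 were higher and 14 lower by camera, 0 held with an estimated correlation or by fry, and another split of these 6 libraries into 3 and 3 gave 27 lists.

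**Figure D2:**
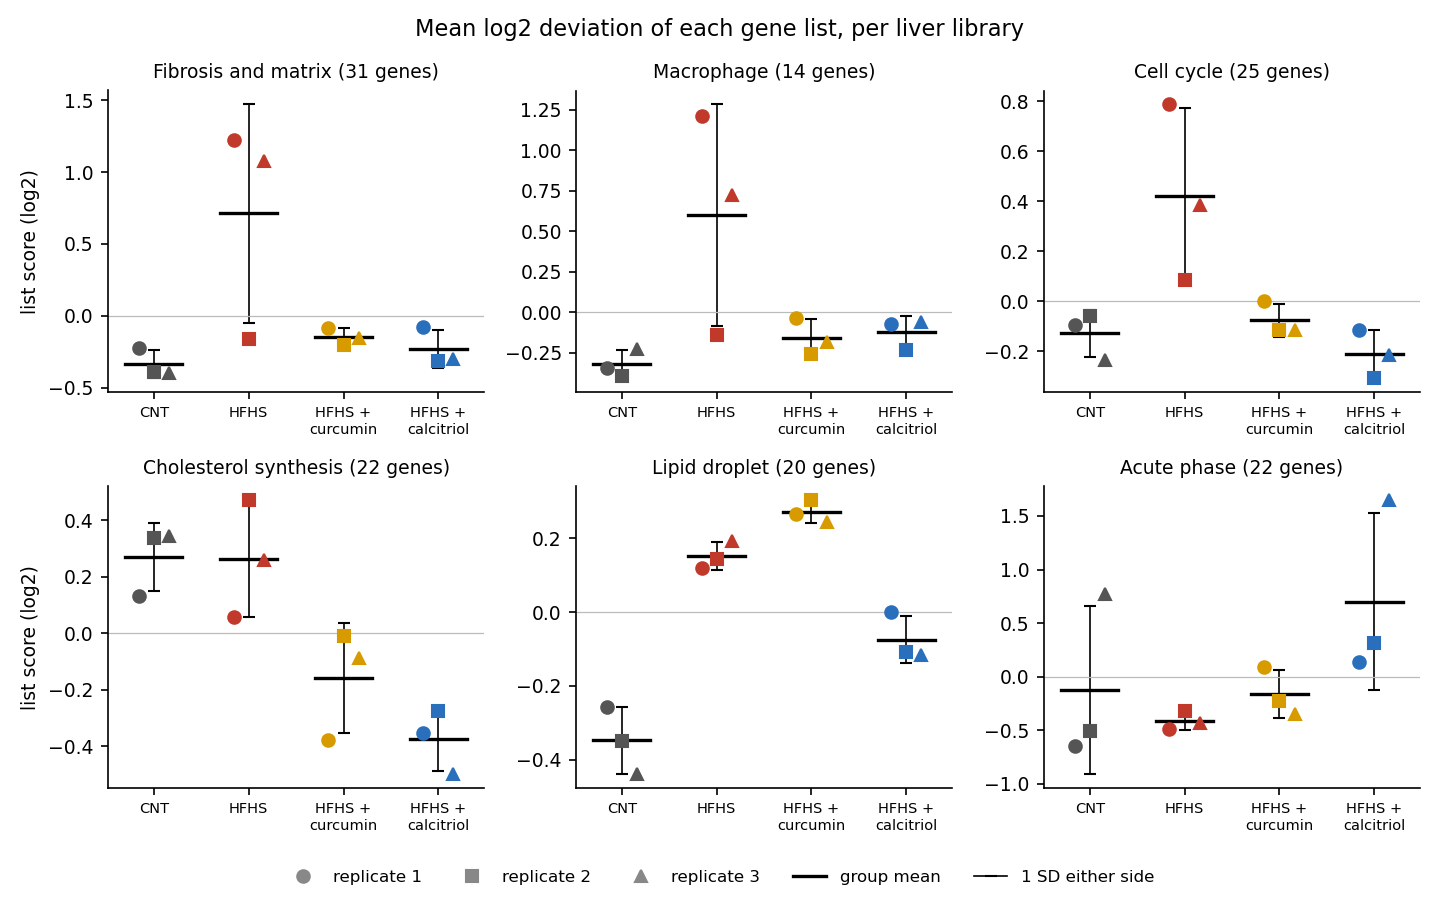
Score of 6 gene lists in each liver library, as the mean log2 deviation of the list's genes from their means over all 12 libraries; points are libraries, bars group means and whiskers 1 SD (n = 3). The fibrosis score is 1.22 and 1.08 in HFHS replicates 1 and 3 and -0.16 in HFHS replicate 2, while the cholesterol synthesis score is below 0 in all 6 treated libraries and above 0 in all HFHS and CNT libraries.

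Calcitriol livers were set against HFHS livers with the same question. The metallothionein genes Mt2 and Mt1, whose products bind zinc and other metals, had the largest rises among genes past the threshold. Mt2 (ENSMUSG00000031762, GRCm38 chromosome 8, 94172664 to 94173568, plus strand) averaged 12.44 ± 0.80 with calcitriol and 9.80 ± 0.33 in HFHS (log2, mean ± SD, n = 3 each), a change of 2.65 ± 0.37 (adjusted p = 0.0163), and neighbouring Mt1 changed by 2.05 ± 0.35 (adjusted p = 0.0249). The scavenger receptor Cd163 (1.92 ± 0.42, adjusted p = 0.047), the acute phase gene Saa4 (1.33 ± 0.26), B3galt1 (1.33 ± 0.25), Itih4 (1.12 ± 0.26), the glutathione-degrading enzyme Chac1 (1.07 ± 0.19) and Acpp (1.06 ± 0.22) also rose. The largest falls were in Gstm3 (-1.75 ± 0.36, adjusted p = 0.0398), a glutathione transferase, Ccnd1 (-1.74 ± 0.24, adjusted p = 0.0163), which encodes cyclin D1, and Cidec (-1.63 ± 0.29, adjusted p = 0.027). Anxa2 (-1.29 ± 0.27), Chrna4 (-1.25 ± 0.26), Slc1a4 (-1.21 ± 0.24) and the mevalonate pathway genes Mvd (-1.24 ± 0.23) and Hmgcs1 (-1.23 ± 0.20, adjusted p = 0.021) followed. The Saa and Gstm genes have close relatives that could share reads. Vdr, the receptor of calcitriol, lay between -0.72 and -0.66 in all 12 libraries, under the level needed for testing, as did Tnf (2.32 to 2.71), and Cyp24a1, a classical target of that receptor, was listed at 0 in all 12.

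Cholesterol synthesis held more genes falling over all genes tested than any other list with calcitriol: all 22 genes had changes below 0, 11 fell over all genes tested and 17 adjusted over the list alone. Lss (-0.81 ± 0.12, adjusted p = 0.0127), Dhcr7 (-0.70 ± 0.11) and Fdps (-0.93 ± 0.15) were among them. By camera the cholesterol synthesis list had adjusted p = 3.40e-16, and adjusted p = 0.532 with an estimated correlation, and fry gave adjusted p = 0.0276. In the cell cycle list 6 of 25 fell, and 22 adjusted over the list alone, with Mcm5 at -1.05 ± 0.13 (adjusted p = 0.00864) and Mcm6 at -1.09 ± 0.14. By camera the cell cycle list had adjusted p = 8.24e-15, and adjusted p = 0.532 with an estimated correlation, and fry gave adjusted p = 0.0307. Of the NRF2 antioxidant targets 9 of 23 fell, and 13 fell and 1 rose adjusted over the list alone, including Gstm4 (-0.75 ± 0.10), Pgd (-0.56 ± 0.09) and Nqo1 (-0.63 ± 0.13, adjusted p = 0.0372). By camera the NRF2 list had adjusted p = 1.32e-08, and adjusted p = 0.444 with an estimated correlation, and fry gave adjusted p = 0.0099. In the heat shock list 3 of 15 fell, and 7 adjusted over the list alone: Hspa1b (-1.03 ± 0.11, adjusted p = 0.00225), Dnajb1 (-0.59 ± 0.09) and Hspa8 (-0.39 ± 0.09). By camera the heat shock list had adjusted p = 2.5e-05, and adjusted p = 0.532 with an estimated correlation. De novo lipogenesis had 1 of 18 falling, Fasn (-0.92 ± 0.17, adjusted p = 0.0297), and 10 falling and 1 rising adjusted over the list alone. By camera the lipogenesis list had adjusted p = 7.75e-05, and adjusted p = 0.545 with an estimated correlation.

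The matrix list and 4 immune lists were also lower with calcitriol, and the acute phase and Kupffer cell lists were higher. Among the NF-kB targets 3 of 20 fell, and 4 adjusted over the list alone, all 3 of them chemokine genes: Cxcl9 (-0.99 ± 0.16, adjusted p = 0.0217), Cxcl10 (-0.86 ± 0.17) and Ccl5 (-0.99 ± 0.20). By camera the NF-kB list had adjusted p = 0.00318, and adjusted p = 0.57 with an estimated correlation. The highest over 9 settings was 0.81, with the direction turned, without HFHS replicates 1 and 3. Il1b (-0.23 ± 0.18, adjusted p = 0.495), Ccl2 (-0.51 ± 0.16, 0.109), Cd68 (-0.17 ± 0.13, 0.506), Nfkbia (-0.14 ± 0.12, 0.541) and Hmox1 (-0.12 ± 0.18, 0.751) did not pass. In the fibrosis and extracellular matrix list 0 of 31 passed over all genes tested, and 25 fell and 1 rose adjusted over the list alone, with Col1a1 at -2.01 ± 0.62 (adjusted p = 0.111). By camera the fibrosis list had adjusted p = 4.47e-13, and adjusted p = 0.532 with an estimated correlation. Its highest value over 9 settings was 0.41, without HFHS replicates 1 and 3. MHC class II genes (0 of 9 passing, 7 falling adjusted over the list alone), macrophage genes (0 of 14 and 3) and T and NK cell genes (1 of 10, Ccl5, and 3) were lower by camera, with adjusted p = 6.59e-06, 0.000591 and 0.00489. The same lists had adjusted p = 0.532, 0.557 and 0.545 with an estimated correlation. Their highest values over 9 settings, 0.441, 0.818 with the direction turned, and 0.466, came without HFHS replicates 1 and 3. In the Kupffer cell list 1 of 16 rose, Cd163, and 3 adjusted over the list alone. By camera the Kupffer cell list had adjusted p = 0.00325, and adjusted p = 0.57 with an estimated correlation. Its highest value over 9 settings was 0.0581, without calcitriol replicate 3.

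In the acute phase list all 22 genes had changes above 0 with calcitriol, 2 rose over all genes tested, Saa4 and Itih4, and 14 adjusted over the list alone. By camera the acute phase list had adjusted p = 1.17e-10, and adjusted p = 0.532 with an estimated correlation. Calcitriol replicate 3 had an acute phase score of 1.65 against 0.14 and 0.31 in calcitriol replicates 1 and 2, and CNT replicate 3 had 0.78 against -0.65 and -0.50. The liver endothelial list, with Clec4g at 0.63 ± 0.13 (adjusted p = 0.038), and the erythroid list, with Alas2, the heme synthesis enzyme of red cells, at 0.57 ± 0.13 (adjusted p = 0.0415), each had 1 gene rising over all genes tested, and 3 of 18 and 7 of 8 adjusted over the list alone. By camera the endothelial and erythroid lists had adjusted p = 0.000508 and 3.06e-06, and adjusted p = 0.57 and 0.532 with an estimated correlation.

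With calcitriol 123 genes rose and 156 fell at an adjusted p under 0.05 in limma, 9 and 15 of them at least 2-fold, and groups did not overlap for 24.4% of genes, where chance gives 10%. The 279 calls became 2194 without HFHS replicate 2, 24 and 58 without HFHS replicate 1 or 3, 118, 4 and 14 without calcitriol replicate 1, 2 or 3, 0 with only the 2 groups in the fit (lowest adjusted p = 0.107, 2310 genes at an unadjusted p under 0.05), and 4 without HFHS replicates 1 and 3. Of 39 lists, 5 were higher and 13 lower by camera, 0 held with an estimated correlation and 3 by fry, and another split of these 6 libraries gave 26 lists.

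**Figure D3:**
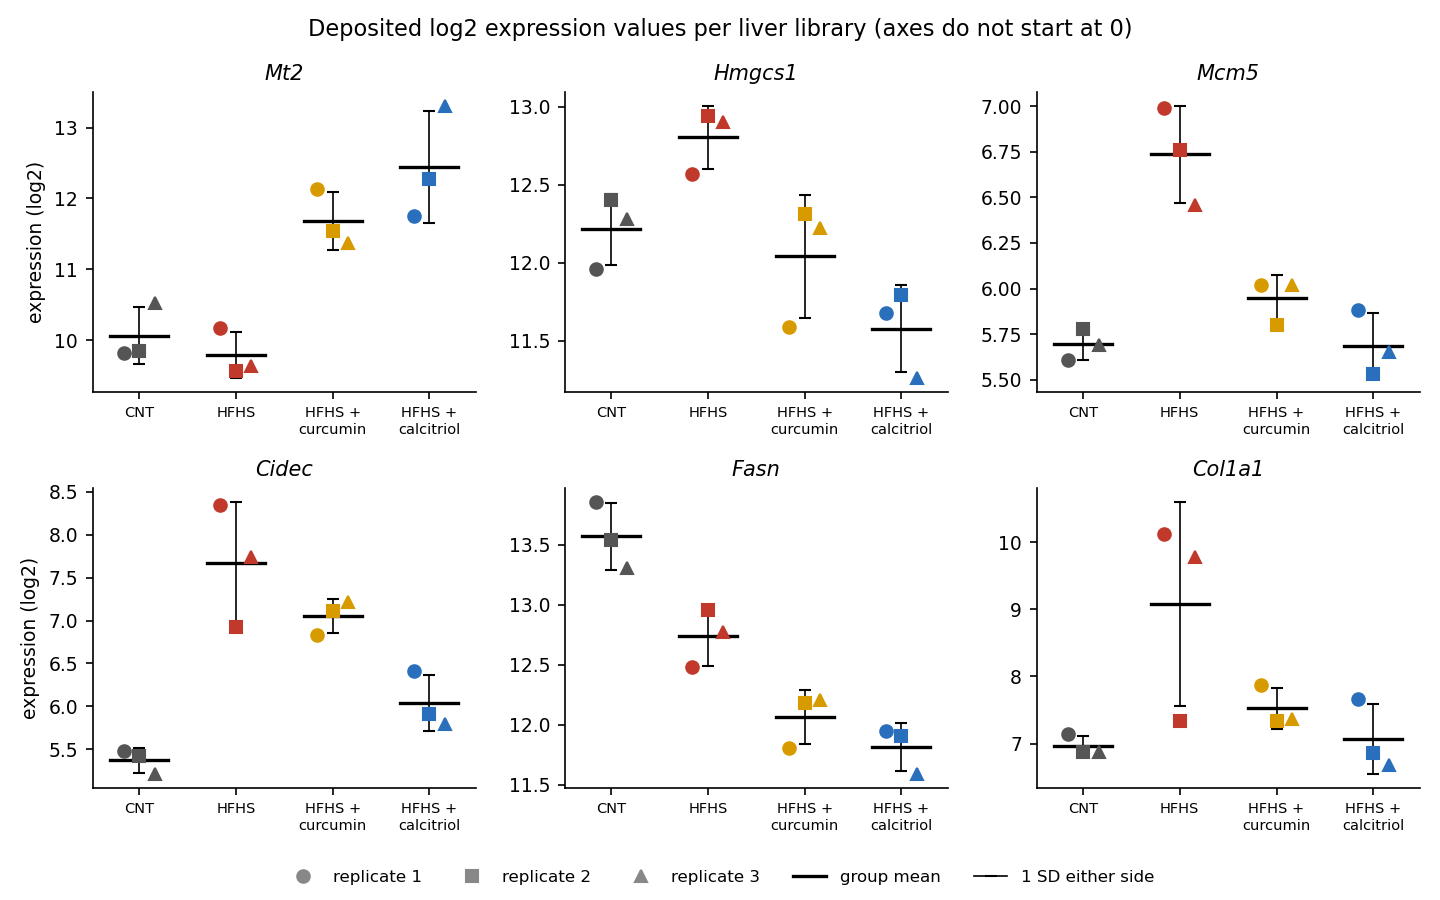
Log2 expression of 6 genes in each liver library; points are libraries, bars group means and whiskers 1 SD (n = 3), and the axes do not start at 0. Mt2 is at least 11.37 in all 6 treated libraries and at most 10.53 in the HFHS and CNT libraries, while Col1a1 is 10.13 and 9.78 in HFHS replicates 1 and 3 and 7.33 in HFHS replicate 2.

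Curcumin and calcitriol livers were compared directly to see whether the treatments differed. No gene passed an adjusted p under 0.05 in limma (lowest 0.142), while 1873 genes had an unadjusted p under 0.05, where chance gives 632, and groups did not overlap for 28.7% of genes, where chance gives 10%. The genes with the smallest p were Gpc1 (0.83 ± 0.13 higher with curcumin; chromosome 1, 92831645 to 92860779), a cell surface proteoglycan gene, Clstn3 (0.73 ± 0.11), Adam23 (-0.76 ± 0.12), Plxnc1 (-0.88 ± 0.14), Tlr8 (-0.69 ± 0.12), Usp12 (-0.34 ± 0.06) and Adgrl4 (-0.79 ± 0.14), all with adjusted p = 0.142, and Kalrn (-0.41 ± 0.07), Zfp236 (-0.48 ± 0.09) and Inhbb (-0.70 ± 0.13) with 0.164. Lipid droplet genes were higher with curcumin: 18 of 20 had changes above 0, 0 passed over all genes tested and 7 rose adjusted over the list alone. By camera the lipid droplet list had adjusted p = 1.1e-06, and adjusted p = 0.0437 with an estimated correlation, and fry gave adjusted p = 0.00551. Cidec had 1.01 ± 0.29 (adjusted p = 0.218) and Plin3 0.32 ± 0.09 (adjusted p = 0.213). All 32 oxidative phosphorylation genes had changes above 0, with 0 passing either adjustment. By camera the oxidative phosphorylation list had adjusted p = 1.3e-12, and adjusted p = 0.683 with an estimated correlation. In the liver endothelial list 17 of 18 genes had changes below 0, 0 passed over all genes tested and 12 fell adjusted over the list alone, with Bmp2 at -0.63 ± 0.12 (adjusted p = 0.164). By camera the endothelial list had adjusted p = 8.86e-11, and adjusted p = 0.683 with an estimated correlation. All 22 acute phase genes had changes below 0, with 0 passing either adjustment. By camera the acute phase list had adjusted p = 1.06e-07, and adjusted p = 0.683 with an estimated correlation. Il1b (-0.08 ± 0.18, adjusted p = 0.872), Ccl2 (0.12 ± 0.16, 0.762), Cd68 (-0.19 ± 0.13, 0.508), Col1a1 (0.45 ± 0.62, 0.763), Nfkbia (0.07 ± 0.12, 0.813), Hmox1 (-0.12 ± 0.18, 0.789) and Nqo1 (0.36 ± 0.13, 0.279) did not pass. With only these 2 groups in the fit, which leaves out the wide spread of HFHS, 53 genes rose and 161 fell; library weights gave 577 calls, and every other setting and each left-out library gave 0. Of 39 lists, 10 were higher and 6 lower with curcumin by camera, 1 held with an estimated correlation and 1 by fry, and another split of these 6 libraries gave 17 lists.

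The treatment effects were also set against each other and against the difference of HFHS from CNT. Of the genes called with curcumin, 11 of the 19 that rose also rose with calcitriol and 12 of the 19 that fell also fell, where independent lists would share 0.185 and 0.235. Mcm5, Mcm6, Hspa1b and Mir22hg were called in the same direction with both. Both treated groups received injected liposomes, so shared changes cannot be assigned to the drugs rather than to the injections or the liposomes. Across genes, which are not independent replicates, the log2 changes of curcumin and calcitriol had a covariance of 0.0483, against 0.0122 ± 0.00943 (SD) in 100 simulations of unchanged groups that share the HFHS libraries, and a correlation of 0.733, against 0.534 on average and up to 0.894 in the simulations. For the difference of HFHS from CNT, 9 of the 19 genes that fell with curcumin and 86 of the 156 that fell with calcitriol had risen in HFHS over CNT, where independent lists would share 1.24 and 10.2. Of the genes that rose, 5 of 19 with curcumin and 36 of 123 with calcitriol had fallen in HFHS, against 1.02 and 6.59. The covariance with that difference was -0.053 for curcumin and -0.05 for calcitriol, against -0.0115 and -0.0108 in the simulations. The HFHS libraries enter both sides of each of these values and cannot be divided with 2 in each part, so the values include the spread of the HFHS libraries themselves. With the wider spread of the HFHS group alone in the simulations, 9, 13 and 5 of 100 gave a covariance as far from 0, and the excess of the shared covariance, 0.0361, became 0.0181, 0.0865 and 0.0245 without HFHS replicate 1, 2 or 3.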

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

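The direction of the calcitriol cholesterol synthesis, cell cycle and NRF2 lists and of the curcumin cell cycle and cholesterol synthesis lists, with their adjusted p under 0.05, held under quantile normalization, the replicate block and each library left out; an estimated correlation removed them. Named genes kept their side of the threshold in 7190 of their values under other settings, passed newly in 544 and no longer passed in 923. The 7190 include genes that passed in neither, while the 923 come only from genes that had passed. None of the genes that had passed turned its direction in these settings, and the direction of the others was not checked. Named genes were not followed without HFHS replicates 1 and 3, so whether they kept their direction there is not known. Counts of called genes moved more, with libraries of every group. For curcumin against HFHS, 38 genes became 74 with no filter, 112 with a stricter filter, 122 with a filter on the mean, 162 with quantile normalization, 242 with the replicate block, 3420 with library weights, 0 with only the 2 groups in the fit and 0 without HFHS replicates 1 and 3 (743 genes at an unadjusted p under 0.05); leaving out 1 library gave 0 to 3207. For calcitriol against HFHS, 279 became 0 with only the 2 groups, 427 with quantile normalization, 2725 with library weights and 4 without HFHS replicates 1 and 3, and 4 to 2194 with 1 library left out. For HFHS against CNT, 1505 became 13 with only the 2 groups, 4790 with library weights and 68 without HFHS replicates 1 and 3, and 135 to 3717 with 1 library left out. For curcumin against calcitriol, 0 in limma (1873 at an unadjusted p under 0.05) became 214 with only the 2 groups and 577 with library weights. The comparisons with CNT gave 2660 (curcumin, from 443) and 3120 (calcitriol, from 511) with library weights, 328 for calcitriol with no filter, and 94 to 949 and 73 to 609 with 1 library left out. With only the 2 groups in the fit fewer libraries estimate the spread, and the wide spread of HFHS enters only its own comparisons. Library weights were lowest for HFHS replicate 2 (0.24) and CNT replicate 3 (0.306). The cause of the other moves was not tested.

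Of the 39 gene lists, the number past the threshold was 0 with an estimated correlation in curcumin against HFHS (from 22), calcitriol against HFHS (from 18), HFHS against CNT (from 31) and calcitriol against CNT (from 17), 1 in curcumin against calcitriol (from 16) and 1 in curcumin against CNT (from 13). By fry the numbers were 0, 3, 10, 7, 1 and 2 in the same order. Without HFHS replicates 1 and 3, 11 lists passed for curcumin against HFHS and 9 for HFHS against CNT, and quantile normalization left 19 for HFHS against CNT. Leaving out 1 library gave 16 to 31 lists for calcitriol against HFHS, with 31 reached without HFHS replicate 2. The excess covariance of the treatment effects, 0.0361, ran from 0.0181 to 0.0865 with 1 library left out. Those with the difference of HFHS from CNT, -0.0415 for curcumin and -0.0391 for calcitriol, ran from -0.099 to -0.022 and from -0.0913 to -0.0186, and the former was -0.0295 with the spread of HFHS alone. All these excesses kept their sign, and the cause of their moves was not tested.

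Libraries with the same replicate number were not treated as pairs: the correlations of their deviations from the group means ran from -0.383 to 0.372, with 9 of 18 over 0.1. All 3 were over 0.1 between HFHS and curcumin (0.16 to 0.321) and between calcitriol and CNT (0.205 to 0.372), and in no other combination of groups. Averaged over the libraries of each number, 10 of 12 libraries correlated best with their own number, a hint from the data and not from the design. Not run, because they need counts, were the size factors of DESeq2, the DESeq2 Wald test and the older quasi-likelihood method. Chosen after seeing the data were median centring, quantile normalization, moderation without robust estimation, library weights, the filter on the mean, leaving out HFHS replicates 1 and 3, the simulated spread of HFHS alone and the comparisons of treated livers with CNT. Where a lone HFHS library was left, it is assumed to vary like the other groups. Depth is unknown, so a limit set by read counts could not be given, and changes of weakly expressed genes are probably understated.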

Other observations

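The comparisons of treated livers with CNT were chosen after the data had been seen, and they do not use the HFHS libraries except for the shared estimate of the spread. Calcitriol livers had lower expression of cholesterol and fatty acid synthesis genes than CNT: 15 of 22 cholesterol synthesis genes fell, and 21 adjusted over the list alone, with Lss at -0.75 ± 0.12 (SE; adjusted p = 0.00806) and Insig1 at -0.83 ± 0.14. By camera the cholesterol synthesis list had adjusted p = 9.93e-16, and adjusted p = 0.401 with an estimated correlation, and fry gave adjusted p = 0.0158. In de novo lipogenesis 8 of 18 fell, and 9 adjusted over the list alone, including Fasn (-1.75 ± 0.17, adjusted p = 0.000521), Elovl6 (-1.34 ± 0.17) and Scd1 (-2.67 ± 0.47, adjusted p = 0.0186). By camera the lipogenesis list had adjusted p = 1.56e-09, and adjusted p = 0.404 with an estimated correlation. Heat shock genes were lower too, with 5 of 15 falling and 11 adjusted over the list alone (Hspa8 -0.61 ± 0.09). By camera the heat shock list had adjusted p = 1.77e-09, and adjusted p = 0.401 with an estimated correlation. Mt2 (2.38 ± 0.37, adjusted p = 0.0109) and Vnn1 (1.08 ± 0.11) rose. In all, 224 genes rose and 287 fell in limma; the 511 calls became 170, 77 and 73 without calcitriol replicate 1, 2 or 3 and 226 and 85 without CNT replicate 1 or 2.

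Curcumin livers had higher fat storage and fat oxidation genes than CNT and lower fat synthesis genes. Of the fatty acid oxidation list 10 of 24 rose, and 17 adjusted over the list alone, including the pantetheinase gene Vnn1 (1.22 ± 0.11, adjusted p = 0.000238) and Cyp4a14 (1.23 ± 0.15). By camera the fatty acid oxidation list had adjusted p = 9.58e-16, and adjusted p = 0.428 with an estimated correlation, and fry gave adjusted p = 0.0203. Of the lipid droplet list 7 of 20 rose, and 11 adjusted over the list alone, including Plin4 (1.88 ± 0.28), Cd36 (1.18 ± 0.12) and Cidec (1.68 ± 0.29). By camera the lipid droplet list had adjusted p = 9.04e-11, and adjusted p = 0.00728 with an estimated correlation, and fry gave adjusted p = 0.000138. The proteoglycan gene Gpc1 rose by 1.91 ± 0.13 (adjusted p = 3.61e-05). Fasn (-1.50 ± 0.17, adjusted p = 0.00123) and Elovl6 (-1.21 ± 0.17) fell, as did 4 of 18 de novo lipogenesis genes in all, and 6 adjusted over the list alone. By camera the lipogenesis list had adjusted p = 0.000121, and adjusted p = 0.779 with an estimated correlation. In cholesterol synthesis 5 of 22 genes fell, and 14 adjusted over the list alone. By camera the cholesterol synthesis list had adjusted p = 4.49e-10, and adjusted p = 0.685 with an estimated correlation. In all, 202 genes rose and 241 fell in limma; the 443 calls became 136, 94 and 121 without curcumin replicate 1, 2 or 3 and 160, 100 and 949 without CNT replicate 1, 2 or 3. The difference of the treatments was tested directly only in the comparison of curcumin with calcitriol, where no gene passed in limma and 1873 had an unadjusted p under 0.05.

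By tests chosen after the results were seen, HFHS replicate 2, which lay with the treated livers in fibrosis and macrophage genes, may be a treated liver under another label. The test used genes called between treated livers and HFHS replicates 1 and 3. HFHS replicate 2 lay beyond the range of the treated libraries, toward HFHS, for 29.6% to 32.5% of them, against 14.4% to 36.9% for a held-out treated library. It exceeded the held-out share in 5 of 6 rounds but not with calcitriol replicate 3 held out, so a treated liver is not excluded. Mt2 was 9.57 in HFHS replicate 2 and at least 11.37 in the 6 treated libraries, and Mcm5 was 6.76 against at most 6.02 outside HFHS. The list scores of HFHS replicate 2 were 0.471 for cholesterol synthesis (treated -0.498 to -0.009), 0.215 for heat shock (at most 0.041) and -0.187 for erythroid genes (at least 0.185). All were picked after their values were seen, from comparisons that counted HFHS replicate 2 as HFHS. Groups did not overlap for any of the 279 genes called with calcitriol, Mt2 and Mcm5 among them. Such values therefore cannot weigh against another label. The same test was made for a CNT liver, over genes called between treated and CNT livers. HFHS replicate 2 lay beyond the CNT range, toward the treated livers, for at least 90.1% of them, against 41.3% to 75.7% for a held-out CNT library. This argues against a CNT liver. With only 3 held-out libraries, each set against the range of 2 others, it does not exclude one. A lower share of hepatocytes in HFHS is left open as a cause of the macrophage difference from CNT: the macrophage list was higher by 0.717 more than the Kupffer cell list, with an SE of 0.225 over genes but 0.393 between libraries, as HFHS replicates 1, 2 and 3 had 1.005, -0.132 and 1.023 for the macrophage minus the Kupffer cell score and CNT -0.256 to 0.058. For HFHS replicate 1 the adipocyte score gave no sign of more adipose tissue than in other samples: its 0.094 lies within the -0.726 to 0.178 of the 9 libraries outside HFHS. A small amount is not excluded, since those 9 were not shown to be free of it. Adipose tissue in the sample is left open for HFHS replicate 3, with 1.852.

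The acute phase test of Mt2 was chosen before the results were seen and the other tests of it after. The injections and the liposomes were not tested as causes. Only the treated groups are labelled as having received them, so they cannot be told apart from the drugs. Mt2 was higher in all 6 treated libraries than in all HFHS and CNT libraries. Its neighbour Mt1 did not separate treated livers from CNT: CNT replicate 3 had 12.33 and curcumin replicate 3 had 12.01. Against CNT, Mt1 did not pass in limma (curcumin 0.704, adjusted p = 0.32, and calcitriol 1.189, adjusted p = 0.0802). An acute phase response, which induces metallothioneins, might be behind the rise of Mt2. With the acute phase score in the limma fit, the change was 1.809 ± 0.26 (adjusted p = 0.0475) with calcitriol, from 2.649. With curcumin it was 1.696 ± 0.204 (adjusted p = 0.0191), from 1.887. As a linear term the score thus did not account for the whole change. Within groups the score varied most in calcitriol (0.138, 0.31 and 1.647) and CNT (-0.649, -0.503 and 0.776), and it measures the response imperfectly. An acute phase response is therefore not excluded as the whole cause. The mean log2 change of 9 glucocorticoid targets was -0.032 with calcitriol (SE 0.225 between libraries, 0.095 over genes) and -0.072 with curcumin (0.231 and 0.149). Each mean plus 2 SE lies under 0.5, the change set for glucocorticoid exposure. With 3 libraries in each group 2 SE is a narrow limit, so a mean change of 0.5 is not firmly excluded. A zinc response may be involved and is left open: the zinc importer gene Slc39a10, which zinc represses, had -0.347 ± 0.104 (adjusted p = 0.0944) with calcitriol and -0.497 ± 0.104 (adjusted p = 0.051) with curcumin, and the exporter gene Slc30a1 was 9.66 to 9.98 in treated livers and 9.39 to 9.40 in HFHS, but also 9.71 to 9.78 in CNT.

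Of clock genes looked up after the data had been seen, Cry1 had a log2 change of 0.97 and Nr1d1 of -0.91 between curcumin and HFHS livers (adjusted p = 0.051 for each), Dbp of -0.22 (0.264) and Tef of 0.09 (0.672), and 0 of 18 in the circadian clock list passed in limma. By camera the circadian clock list had adjusted p = 0.101, and adjusted p = 0.645 with an estimated correlation. Against CNT, Nr1d1 fell with curcumin (-1.15 ± 0.18, adjusted p = 0.00804) and calcitriol (-0.91 ± 0.18, 0.0237), and Dbp fell with curcumin (-0.75 ± 0.12, 0.00664), with calcitriol (-0.83 ± 0.12, 0.00521) and in HFHS (-0.53 ± 0.12, 0.0211). In HFHS against CNT 5 of 18 clock genes fell, and 8 adjusted over the list alone. There the clock list was lower by camera with adjusted p = 0.00132, and adjusted p = 0.504 with an estimated correlation, and its highest value over 9 settings was 0.0776, without HFHS replicates 1 and 3. The hour at which each liver was taken is not in the labels.

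The splits of the libraries were planned before the results were seen. Each comparison has 10 splits of its 6 libraries into 3 and 3, which cannot give a share under 0.1. The real split gave 38 genes against at most 0 in the others for curcumin with HFHS, 279 against 3 for calcitriol with HFHS, 1505 against 79 for HFHS with CNT, 443 against 20 for curcumin with CNT and 511 against 0 for calcitriol with CNT, so 1 of 10 was as large in each; for curcumin with calcitriol all 10 gave 0. For gene lists, 4 of 10 splits were as large for curcumin with HFHS (22, highest other 27), 6 for calcitriol with HFHS (18, highest other 26), 1 for HFHS with CNT (31, highest other 27), 4 for curcumin with calcitriol (16, highest other 17), 4 for curcumin with CNT (13, highest other 18) and 3 for calcitriol with CNT (17, highest other 18). For the covariances, the real split of 9 libraries into groups of 3 and others drawn at random made up 100 splits. For the treatment effects 3 of them, the real split included, gave a covariance as large (real 0.0483, highest other 0.0556). That is under the share of 0.05 set beforehand. The 100 are only a sample of the possible splits, so a chance division of the libraries is not firmly excluded. The spread of the shared HFHS libraries is left open as well. With the spread of HFHS alone, 9 of 100 simulations were as far from 0, and 9 and 6 without HFHS replicate 1 or 3. For the covariance with the difference of HFHS from CNT, 5 of 100 splits were as far below 0 for curcumin (real -0.053, furthest other -0.062). For calcitriol 5 were as well (real -0.05, furthest other -0.0616). Both counts include the real split, and chance could not be excluded.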
